A study of Homo sapiens with 6 samples.

How the data were processed

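RNA from H295R cells treated for 24 h with 5 µM CX-4945 or with DMSO was measured on 6 whole-transcript arrays, 3 per group. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was amplified and labelled with biotin by a whole-transcript kit. Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console; its version, its normalization and background settings, and the genome build are not given in the sources used here. The deposited values were intensities on a linear scale, 1 per row and array, between 6.41 and 919660. They were taken as already normalized by the authors, since the array medians lay close together. Because the method is unknown, a fold here is a fold on the authors' scale, and it may be compressed near the background or stretched by the summarization.

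The log2 of each deposited intensity was taken with no pseudocount and no further scaling. A table of the platform's annotation named 37295 of 135750 rows, of which 36176 had 1 gene symbol and 1119 several. The other 98455 rows are unnamed here and were tested only as rows. Symbols were checked through gene identifiers against the RefSeq annotation of GRCh38.p14, which matched 25516 of the rows with 1 symbol and changed 0 symbols. That annotation was also used for biotypes, for the span of a gene and for which genes lie inside others; since the build of the array rows is not known, no coordinates are given. Of 1576 genes with several rows, the row with the highest mean over the 6 arrays stood for the gene. In 19 of these genes, rows were called in opposite directions. This left 33616 genes, with no filter on dim rows. No column of values was left unmatched to a sample.

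CX-4945 was compared with DMSO by limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Differences are CX-4945 minus DMSO on the log2 scale with the SE of the fit, and levels are means ± SD of 3 arrays. The fit leaves 4 residual degrees of freedom. A count of genes changed at least 2-fold adds an absolute log2 difference of 1 to that test. NR5A1 was also tested by an exact permutation of its 6 values. Gene lists were compared with all other genes by camera in limma with a preset correlation of 0.01, and adjusted over the 39 lists with at least 3 measured members. The 40 lists, with 879 entries of which 786 were measured, came from textbook knowledge of the cell line, the compound, stress and growth pathways and markers of other cell types. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 highest and 12 lowest log2 differences among called genes whose groups did not overlap, leaving out uncharacterised, pseudogene, antisense and small RNA symbols. It also took NR5A1, all steroidogenic genes, all adrenocortical transcription factors and the CK2 subunits, and up to 4 members with the smallest adjusted p of each other list (2 where the list did not pass). It gave 156 genes, all named in the text.

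As a background level, the 95th percentile of the mean of 374 olfactory receptor genes was used, a log2 intensity of 6.40; 17337 genes lay above it in at least 1 group. This level was chosen after seeing the data. Of the olfactory receptor genes themselves 14 were called changed, and their median log2 difference was 0.04. For arrays, their number limits the precision. The median SD over genes was 0.18 in DMSO and 0.23 in CX-4945. No pair of arrays had more than 15 rows with exactly equal values, counted over all rows. The fit was tried on simulated data with the moderated spread of these genes. In them 200 of 33616 genes were changed in the comparison of CX-4945 with DMSO, besides a small list shifted together. It recovered 19.4% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 100% of those changed 4-fold. There were 9 false calls, with the shifted list left out. In the real data 22.8% of genes were called, which makes the cut-off of the adjustment less strict. Neither the recovery nor the number of false calls therefore carries over to the real data. Scan dates are not given in the sources used here, so no batch could be tested.

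The alternatives were quantile normalization, equal array medians, no intensity trend, no moderation, filters at the median and the 25th percentile of gene levels, the mean of a gene's rows, all rows, the replicate number as a block, array weights, leaving out each array, treat against a fold of 1.2, camera with an estimated correlation, and fry. A filter at the olfactory receptor level was added after seeing the data. Plots were drawn with matplotlib 3.10.9.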

Results

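Gene-level RNA was measured on microarrays in H295R cells, a human adrenocortical carcinoma line that makes steroid hormones. The cells had been exposed for 24 h to 5 µM CX-4945 or to its solvent DMSO. CX-4945 (silmitasertib) inhibits the protein kinase CK2 and is also known to inhibit CLK kinases, which phosphorylate splicing factors. There were 3 arrays per group. The title of the series concerns NR5A1, the nuclear receptor that drives steroidogenic genes, its circular RNA and its exon skipping. The rows analysed here give 1 level per gene, so they do not tell circular RNA or RNA with skipped exons apart from other RNA of the gene. The question they address is which genes differed in level between treated and solvent-exposed cells. Each array held 135750 rows, with a median intensity of 40.7 to 43.1 in DMSO and 45.8 to 46.5 in CX-4945. Across genes, which are not independent replicates, the DMSO arrays correlated at r = 0.994 with each other. CX-4945 replicates 1 and 3 also correlated at 0.994, whereas replicate 2 correlated with them at 0.988 and 0.990. The number of arrays limits the precision of every value. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

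The levels of many genes differed between CX-4945 and DMSO. Lower were 16 of 19 measured genes of cholesterol synthesis, 13 of 19 Wnt target genes and 9 of 19 genes of steroid synthesis. Higher were 19 of 25 genes of the integrated stress response, 15 of 23 immediate early genes and 12 of 16 feedback genes of the MAP kinase pathway. These 6 lists passed the list test with a preset correlation, and none passed with an estimated correlation (adjusted p = 0.128 to 0.524). Among the highest rises were CGA, the alpha subunit of the glycoprotein hormones, at 55.6-fold (log2 difference 5.80 ± 0.23 SE), the stress pseudokinase TRIB3 at 51.8-fold, the transcription factor EGR1 at 37.0-fold and the receptor kinase EGFR at 29.4-fold. Among the deep falls were those of BRINP2 (log2 difference -6.88 ± 0.17), the Wnt antagonist APCDD1 (-6.72 ± 0.17), the cholesterol side-chain cleavage enzyme CYP11A1 (-6.33 ± 0.20) and the steroid sulfotransferase SULT2A1 (-6.26 ± 0.23, to below background). Of 33616 genes tested with limma, 7665 (22.8%) passed an adjusted p of 0.05. Of these, 3469 were higher and 4196 lower with CX-4945. An estimated change of at least 2-fold was found for 3816 of them, with 1459 higher and 2357 lower. Without CX-4945 replicate 2, the treated array that correlated least with the others, 8921 genes were called changed. All 3 treated values lay on one side of all 3 DMSO values in 36.02% of genes, against 10% by chance. Among 17579 protein-coding genes, 2094 were higher and 3575 lower. Among 9273 pseudogenes the balance was the other way, with 790 higher and 314 lower. Some pseudogenes, such as several U6 copies, had identical log2 differences and SEs, so not all of them are separate measurements. Their balance was not recounted under other scalings.

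The balance of rises and falls depended on how the arrays were put on a common scale. The median log2 difference over all genes was 0.02 as deposited, -0.09 after quantile normalization and -0.11 with equal array medians. With quantile normalization 2624 genes were higher and 5271 lower, and with equal medians 2539 were higher and 5291 lower. The share of rises among the calls was thus 33.2% and 32.4%, compared with 45.3% as deposited. Values below are on the deposited scale, so small differences of either sign should be read against these medians.

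**Figure D1:**
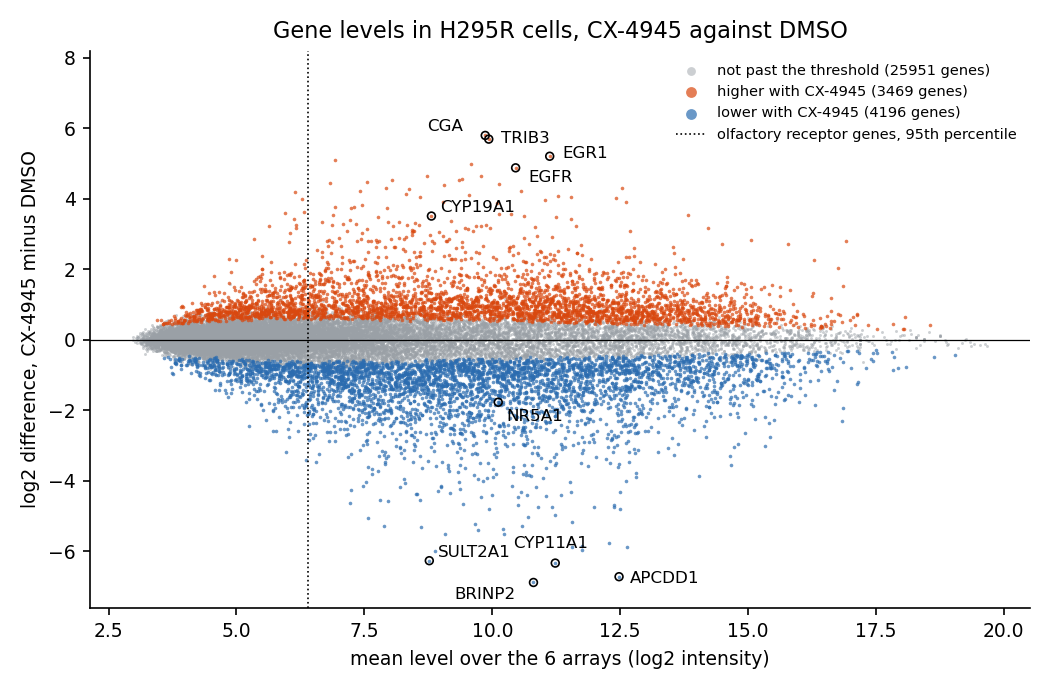
Each point is 1 of 33616 genes, with its mean level over the 6 arrays (log2 intensity) on the x axis and its log2 difference, CX-4945 minus DMSO, on the y axis; orange points are the 3469 genes that were higher, blue points the 4196 that were lower and grey points those past no threshold. The dotted line marks the 95th percentile of 374 olfactory receptor genes, used as a background level. BRINP2 and APCDD1, both above that level in each group, lie farther from 0 than CGA, the highest rise under the rule for named genes.

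The row of NR5A1, which does not tell the forms of its RNA apart, was 3.41-fold lower with CX-4945. Its intensities were 2162, 2517 and 1583 on the DMSO arrays and 498.6, 936.2 and 466.7 on the CX-4945 arrays, with an SD on the log2 scale of 0.34 and 0.55 (n = 3 each). The log2 difference was -1.77 ± 0.27 (SE), with a limma adjusted p of 3.87e-04, and all 3 treated arrays lay below all 3 DMSO arrays. A two-sided exact permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 arrays allow. Without moderation of the variance the adjusted p was 0.0628, the highest of its alternatives, which ranged from 4.31e-06.

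Of 19 measured enzymes and cofactors of steroid synthesis, 9 were lower, 2 higher and 8 past no threshold. Adjusted over the list alone, 10 were lower and 3 higher. As a list they were lower, with a mean log2 difference of -1.15 (camera adjusted p = 8.37e-04; adjusted p = 0.524 with an estimated correlation). CYP11A1, which starts steroid synthesis from cholesterol, fell 80.5-fold. CYP17A1, the 17-hydroxylase that leads to cortisol and androgens, fell 25.8-fold (log2 difference -4.69 ± 0.22). SULT2A1, which sulfates DHEA, fell 76.8-fold as measured, but to below the background level of the olfactory receptor genes, so that the size of its fall depends on that floor. The reductase AKR1C3 fell 8.12-fold and HSD3B2, the adrenal 3-beta-hydroxysteroid dehydrogenase, 4.14-fold. STAR, the protein that carries cholesterol into mitochondria, fell 2.59-fold. Smaller falls were those of H6PD (log2 difference -0.86), HSD3B1 (-0.83) and CYB5A (-0.61). Each of these 3 lost its call in some alternatives, with adjusted p up to 0.15, 0.0964 and 0.112, and HSD3B1 lay below background in both groups. CYP19A1, the aromatase that makes estrogens, rose 11.4-fold (log2 difference 3.51 ± 0.19). CYP21A2 gave a log2 difference of 0.83 ± 0.22, but it shares most of its sequence with a pseudogene and its call was lost without DMSO replicate 1 (adjusted p 0.067), without DMSO replicate 3 (0.0859) and without moderation (0.168, the highest of its alternatives). The near-identical aldosterone and cortisol enzymes CYP11B2 and CYP11B1 had means below background in both groups. FDX1 (log2 difference -0.05), FDXR (-0.12), PAPSS2 (-0.12), HSD17B1 (-0.14), HSD17B3 (0.60) and SRD5A1 (-0.49) did not pass the test. SRD5A1 passed in 4 of 16 alternatives, among them quantile normalization (log2 difference -0.66, adjusted p 0.0248) and equal medians (-0.62, 0.0334), and HSD17B3 passed without DMSO replicate 1 (0.0264).

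**Figure D2:**
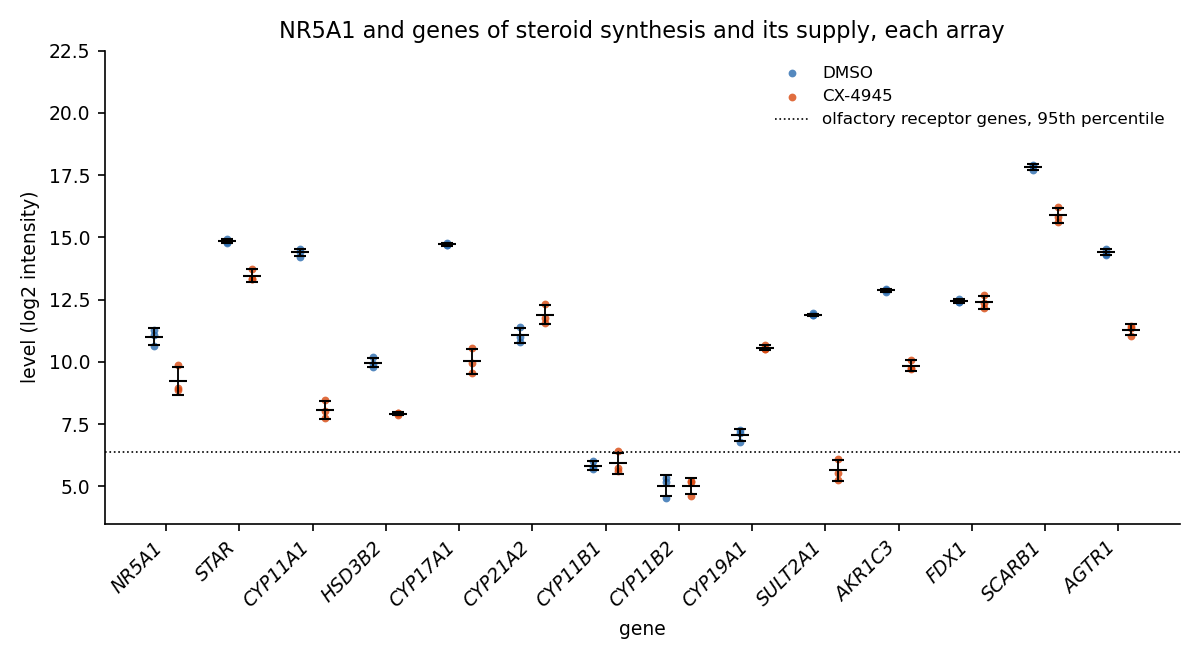
Points are the log2 intensities of the 3 DMSO (blue) and 3 CX-4945 (orange) arrays for NR5A1, 11 genes of steroid synthesis, the lipoprotein receptor SCARB1 and the angiotensin receptor AGTR1, with the mean and SD as bars. CYP11A1 and CYP17A1 had log2 differences of -6.33 and -4.69, SULT2A1 fell to below the dotted background level, CYP19A1 rose from near that level, and the means of CYP11B1 and CYP11B2 lay below it in both groups.

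Of 20 measured receptor and signalling genes of the adrenal cortex, 11 were lower and 1 higher, with the same counts when adjusted over the list alone. The angiotensin II receptor AGTR1 fell 8.68-fold, the potassium channel gene KCNJ5 12.3-fold, the calcium-binding protein gene CALN1 16.6-fold and the phosphodiesterase gene PDE11A 9.49-fold, CALN1 and PDE11A to below background. The list was lower (camera adjusted p = 2.71e-05; adjusted p = 0.128 with an estimated correlation). Transcription factors of the adrenal cortex and partners of NR5A1 went both ways, with 3 higher and 7 lower of 16 measured, 3 and 7 also when adjusted over the list alone. The list did not pass (camera adjusted p = 0.254). The orphan receptor NR4A2 rose 23.0-fold, its relative NR4A1 2.82-fold and the coregulator CITED2 15.1-fold, whereas NR4A3 fell 3.93-fold. SREBF1, the sterol and fatty acid regulator, fell 4.81-fold. DACH1 was lower by a log2 difference of -1.81 ± 0.17 on its brighter row, whereas its other row gave only -0.33. CREM (log2 difference -0.76), NR2F1 (-0.91) and SP1 (-0.47) were lower. The calls of NR2F1 and SP1 were each lost in 4 of 16 alternatives. NR5A2 (0.15), NR0B2 (-0.27), GATA4 (0.21), GATA6 (-0.17), WT1 (0.04) and CREB1 (-0.23) did not pass. Of the CK2 subunits, CSNK2A1 differed by 0.33 ± 0.11, a call lost in 9 of 16 alternatives (adjusted p up to 0.225), and CSNK2A2 by -0.02 ± 0.13. With 2 measured members the CK2 list was too short for the list test.

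Of 19 measured genes of cholesterol synthesis, 16 were lower and none was higher, also when adjusted over the list alone. Lanosterol synthase LSS fell 7.86-fold, the sterol oxidase MSMO1 4.54-fold, mevalonate kinase MVK 4.17-fold and ACAT2, the thiolase at the start of the pathway, 3.49-fold. The list was lower with a median log2 difference of -1.46 (camera adjusted p = 3.87e-11; adjusted p = 0.128 with an estimated correlation). Genes of cholesterol uptake, storage and efflux did not pass as a list (camera adjusted p = 0.263), with 2 higher and 4 lower of 12, or 3 and 4 when adjusted over the list alone. Among them the lipoprotein receptor SCARB1 fell 3.85-fold from a log2 intensity of 17.8 ± 0.12 in DMSO. The lipase LIPE fell 5.27-fold to below background.

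Genes of the integrated stress response, which ATF4 switches on when amino acids are short or the endoplasmic reticulum is stressed, rose in most members. Of 25 measured, 19 were higher and 2 lower, or 20 and 2 when adjusted over the list alone. TRIB3 and CHAC1, which degrades glutathione (31.5-fold), rose, as did the leucine sensor SESN2 (25.3-fold), the transcription factor DDIT3 or CHOP (21.5-fold) and the one-carbon enzyme MTHFD2 (9.09-fold). The cystine transporter SLC7A11 rose 6.19-fold. The list was higher with a median log2 difference of 1.79 (camera adjusted p = 2.85e-16; adjusted p = 0.128 with an estimated correlation). Of 20 chaperones and other genes of the unfolded protein response, 7 were higher and 2 lower, or 8 and 2 when adjusted over the list alone. XBP1 rose 5.07-fold, DNAJB9 2.17-fold and HERPUD1 2.13-fold, while the disulfide isomerase PDIA3 fell 1.88-fold. This list passed (camera adjusted p = 0.0229), but not with an estimated correlation (adjusted p = 0.57). It was also lost without DMSO replicate 3 (0.0811), without CX-4945 replicate 2 (0.0823), with the mean of a gene's rows (0.076) and with a filter at the olfactory receptor level (0.0656).

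Of 23 measured immediate early genes, which growth factors and stress induce within minutes to hours, 15 were higher and 1 lower at 24 h, or 16 and 2 when adjusted over the list alone. EGR1, NR4A2, JUN (16.6-fold) and ATF3 (8.81-fold) were among the rises. The list was higher (camera adjusted p = 1.32e-08; adjusted p = 0.524 with an estimated correlation). Of 16 genes that MAP kinase signalling induces as its own brakes and effectors, 12 were higher and 1 lower, also when adjusted over the list alone. The Sprouty and Spred genes SPRY4 and SPRED2 rose 17.5-fold and 9.35-fold, the phosphatase gene DUSP5 8.47-fold and the transcription factor ETV5 7.10-fold. This list was higher with a median log2 difference of 1.82 (camera adjusted p = 2.51e-08; adjusted p = 0.146 with an estimated correlation). Other rises among the top 12 under the rule for named genes were those of the activin subunit INHBA (23.1-fold), the G protein regulator RGS4 (22.1-fold), PALM2AKAP2 (23.6-fold), the sperm channel gene CATSPERD (34.4-fold) and the noncoding RNA LINC01599 (25.3-fold). RGS4, CATSPERD, NR4A2, LINC01599, ATF3 and SPRY4 were below background in DMSO, so their folds depend on that floor. INHBA had an SD of 0.82 over the treated arrays (n = 3), the highest of the genes named here.

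H295R cells carry an activating beta-catenin mutation. Of 19 measured Wnt/beta-catenin target genes, 13 were lower and 2 higher, or 13 and 3 when adjusted over the list alone. APCDD1 fell 105.2-fold, the stem cell receptor LGR5 39.4-fold to below background, the pathway inhibitor AXIN2 17.5-fold and the growth factor BMP4 4.87-fold. The list was lower with a median log2 difference of -1.85 (camera adjusted p = 1.38e-08; adjusted p = 0.128 with an estimated correlation). The other falls among the 12 lowest measured log2 differences under the rule for named genes were those of the receptor gene GPR22 (63.8-fold, to below background), the cytidine deaminase gene APOBEC3C (61.8-fold), MUCL1 (58.3-fold), the glutamate receptor subunit GRIN3A (57.0-fold), the TGF-beta binding protein LTBP1 (54.7-fold), CDK15 (45.8-fold, to below background) and the noncoding RNA TH2LCRR (45.4-fold). The treated levels of SULT2A1, GPR22, CDK15, LGR5, CALN1, PDE11A, LIPE and IFI44L lay below background, so their folds depend on that floor and give no order among the falls. ZNF385A fell 59.0-fold on its brighter row and by 4.07 on the log2 scale on its other row.

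**Figure D3:**
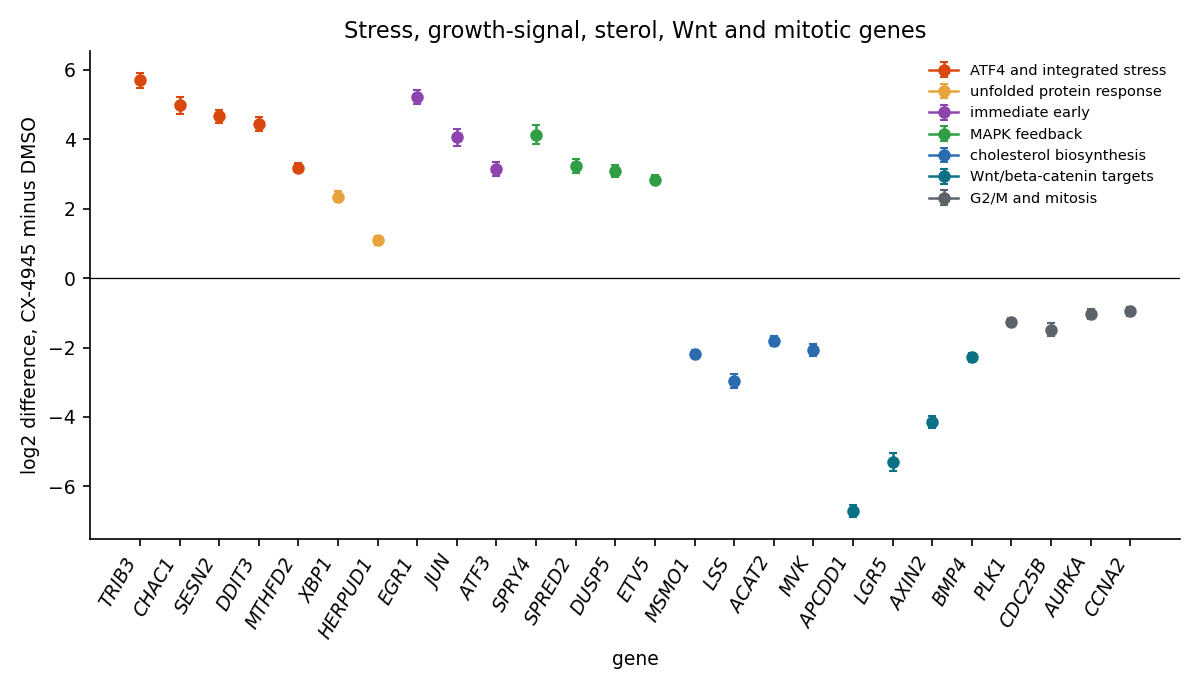
Points show the log2 difference, CX-4945 minus DMSO, of 26 named genes with the SE of the limma fit as bars (3 arrays per group), coloured by gene group. The stress, immediate early and MAP kinase feedback genes drawn lie between 1.09 and 5.69, and the sterol, Wnt target and mitotic genes drawn between -6.72 and -0.96. These ranges depend on the genes chosen. Of the unfolded protein response XBP1 and HERPUD1 are drawn, while PDIA3, which fell, and DNAJB9, which rose, are not. Most of these lists also hold members called in the other direction.

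Of 32 measured genes of G2/M and mitosis, 12 were lower and 1 higher, or 16 and 1 when adjusted over the list alone. The kinases PLK1 and AURKA fell 2.40-fold and 2.05-fold, the phosphatase CDC25B 2.81-fold and cyclin CCNA2 1.94-fold. The list was lower (camera adjusted p = 2.71e-05; adjusted p = 0.146 with an estimated correlation). Of 21 replication-dependent histone genes, 12 were lower and 1 higher, or 14 and 1 when adjusted over the list alone, with H1-3 down 3.22-fold, H2BC5 2.90-fold, H2BC14 1.90-fold and H2AC20 1.60-fold. Histone genes resemble one another in sequence, so members may share signal. The histone list was lower (camera adjusted p = 1.55e-05; adjusted p = 0.524 with an estimated correlation). The G1/S and DNA replication list did not pass (camera adjusted p = 0.137), with 4 higher and 9 lower of 33, or 5 and 9 when adjusted over the list alone. Within it the ribonucleotide reductase subunit RRM2 fell 3.76-fold and cyclin CCNE1 3.44-fold. Without CX-4945 replicate 2 this list passed (adjusted p 0.0208).

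Of 15 CLK, DYRK and SRPK kinase genes, 7 were higher and 2 lower, or 9 and 3 when adjusted over the list alone. CLK1, CLK2 and CLK3 rose 2.95-fold, 2.17-fold and 2.18-fold, and HIPK2 fell 2.83-fold. The list passed (camera adjusted p = 0.0398; adjusted p = 0.524 with an estimated correlation), but not without DMSO replicate 1 (0.0748), DMSO replicate 3 (0.0738) or CX-4945 replicate 3 (0.0558), nor with any of 3 filters on dim genes (0.0638 to 0.0989). Of 21 hnRNP genes, 8 were lower and 2 higher, or 8 and 3 when adjusted over the list alone. HNRNPL fell 8.15-fold, HNRNPD 5.12-fold, HNRNPDL 2.87-fold and HNRNPA1 1.75-fold. That list was lower (camera adjusted p = 0.0186; adjusted p = 0.524 with an estimated correlation), but not without DMSO replicate 2 (0.0691), without the intensity trend (0.0537) or with filters at the median (0.124) or the olfactory receptor level (0.123). SR proteins did not pass (3 higher and 4 lower of 16, also when adjusted over the list alone; camera adjusted p = 0.52), although TRA2A fell 3.44-fold and SRSF1 2.04-fold. The core spliceosome did not pass either (9 higher and 5 lower of 35, or 9 and 6 when adjusted over the list alone; camera adjusted p = 0.349). Its members with the smallest p went opposite ways, with PRPF8 down 6.18-fold and PRPF3 up 2.45-fold. Regulators of back-splicing, the reaction that makes circular RNA, had 2 higher and 4 lower of 10, also when adjusted over the list alone, with QKI down 2.10-fold. Their list did not pass (camera adjusted p = 0.332); its test and mean pointed down and its median, 0.10, up.

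Of 26 nuclear-encoded genes of oxidative phosphorylation, 13 were lower and none higher, or 14 and none when adjusted over the list alone. NDUFB5 fell 5.08-fold, NDUFB8 4.92-fold, SDHC 4.88-fold and UQCRC2 3.36-fold. The list was lower (camera adjusted p = 1.60e-07; adjusted p = 0.524 with an estimated correlation). Of 8 measured genes encoded in mitochondrial DNA, 3 were higher and none lower, also when adjusted over the list alone. ND2 rose 1.69-fold and ND3 1.62-fold (ND3 not without moderation, adjusted p 0.123), and the list did not pass (camera adjusted p = 0.52; test and mean up, median -0.07). Hypoxia and glycolysis genes had 9 lower and 3 higher of 26, also when adjusted over the list alone. ALDOC fell 5.55-fold, BNIP3L 4.07-fold and PDK1 3.58-fold, and NDRG1 rose 3.77-fold from below background. This list was lower (camera adjusted p = 0.0153; adjusted p = 0.572 with an estimated correlation), with an adjusted p of 0.0502 without CX-4945 replicate 3. Of 26 cytosolic ribosomal protein genes, 9 were higher, none lower and 17 past no threshold, also when adjusted over the list alone. RPS14 rose 2.57-fold, RPL5 1.96-fold, RPL24 1.52-fold and RPL18 1.36-fold, a call lost with equal medians (0.054) and without the intensity trend (0.0697). These genes have many processed pseudogenes that may share signal. The list was higher (camera adjusted p = 0.00174; adjusted p = 0.57 with an estimated correlation). Ribosome biogenesis genes did not pass as a list (5 higher and 2 lower of 22, or 6 and 2 when adjusted over the list alone; camera adjusted p = 0.115), with PES1 up 2.74-fold and RRN3 up 2.42-fold.

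Of 22 interferon response genes, 8 were lower, 1 higher and 13 past no threshold, or 8 and 3 when adjusted over the list alone. IFI44L fell 39.2-fold to below background, BST2 11.8-fold, IFIT1 8.66-fold and IFI44 4.66-fold. The list was lower (camera adjusted p = 0.00105; adjusted p = 0.128 with an estimated correlation).

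**Figure D4:**
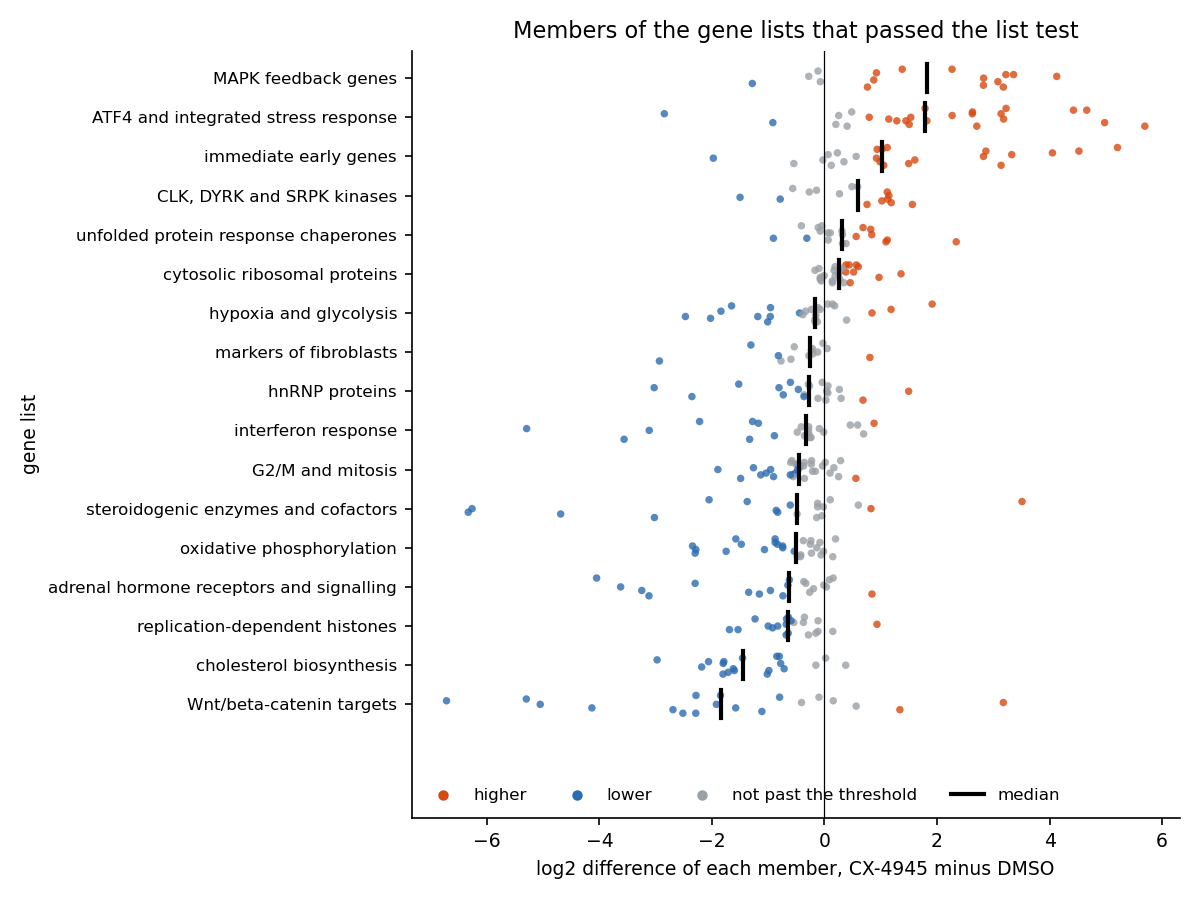
Each row is 1 of the 17 gene lists that passed the list test with the preset correlation, and each point is the log2 difference of a measured member, CX-4945 minus DMSO, with higher calls in orange, lower calls in blue, other members in grey and the median as a bar. The 6 higher lists have medians of 0.26 to 1.82 and the 11 lower lists medians of -1.85 to -0.17, and each list holds at least 3 members that did not pass.

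The remaining lists did not pass the list test but held strong changes in single genes. Among p53 target genes, 6 were higher and 7 lower of 24, or 6 and 8 when adjusted over the list alone (camera adjusted p = 0.834; test and mean up, median -0.01). GADD45A rose by a log2 difference of 4.09 ± 0.20. Apoptosis regulators had 3 higher and 4 lower of 23, also when adjusted over the list alone (camera adjusted p = 0.647), with MCL1 up 2.02-fold and CASP9 down 2.68-fold. The heat shock list had 1 higher and 3 lower of 16, or 2 and 3 when adjusted over the list alone (0.205), with log2 differences of -3.84 for HSPB8 and -1.81 for HSPA4L. NRF2 targets had 6 higher and 7 lower of 17, also when adjusted over the list alone (0.508), with ME1 down 3.54-fold and SLC7A11, which the stress response list also holds, up 6.19-fold. Aryl hydrocarbon receptor targets had 4 higher and 2 lower of 9, also when adjusted over the list alone (0.205), with TIPARP up 3.42-fold and the receptor's partner ARNT down 2.07-fold. NF-kB targets had 5 higher and 2 lower of 19, also when adjusted over the list alone (0.399), with TNFAIP3 up 2.96-fold and CD83 down 3.23-fold. FOXO targets and PI3K feedback genes had 7 higher and 5 lower of 22, or 10 and 6 when adjusted over the list alone (0.168). CCNG2 rose 3.05-fold, but its other row gave a log2 difference of only 0.59.

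The IGF system had 1 higher and 6 lower of 16, or 1 and 7 when adjusted over the list alone (camera adjusted p = 0.0664), with IGF2R down 2.75-fold and IGF2BP3 down 2.42-fold. It passed without DMSO replicate 1 (0.037) or CX-4945 replicate 2 (0.0246). Autophagy and lysosome genes had 6 higher and 5 lower of 25, or 8 and 6 when adjusted over the list alone (0.805). MAP1LC3B rose 2.73-fold on its brighter row and differed by -0.04 on the other, and CTSL fell 2.44-fold. DNA repair genes had 2 higher and 7 lower of 24, also when adjusted over the list alone (0.349; test and mean down, median 0.07). XRCC1 fell 7.49-fold and PRKDC 3.71-fold, the latter not without moderation (0.0666). Epithelial-mesenchymal and matrix genes had 5 higher and 9 lower of 23, or 5 and 10 when adjusted over the list alone (0.107), with SNAI2 down 5.36-fold and LAMC1 down 3.22-fold.

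Markers of cell types other than the line were tested as a check of cell composition. Fibroblast markers were lower as a list (3 lower and 1 higher of 14, also when adjusted over the list alone; camera adjusted p = 0.0417; adjusted p = 0.524 with an estimated correlation). That call was lost in 10 of 17 alternatives, among them each left-out array except DMSO replicate 2 and CX-4945 replicate 1 (0.0561 to 0.134). ACTA2 fell 7.64-fold and FAP 2.48-fold (the latter not without moderation, 0.0818), while THY1 differed by -0.82 on the log2 scale below background in both groups, and DCN rose 1.75-fold. Chromaffin and neuroendocrine markers had 2 higher and 2 lower of 18, also when adjusted over the list alone (camera adjusted p = 0.399), with CHGB down 2.86-fold and SCG2 higher by 2.27 on the log2 scale below background in both groups. Leukocyte markers had 3 higher and 1 lower of 18, also when adjusted over the list alone (0.484), with FCER1G up 7.04-fold and CD14 up 3.20-fold from below background. Endothelial markers had 1 higher and 1 lower of 14, also when adjusted over the list alone (0.838; test and median down, mean 0.10), with FLT1 up 9.61-fold as measured from below background and EMCN lower with a log2 difference of -0.67 below background in both groups, a call lost in 5 of 14 alternatives. The folds of FCER1G, CD14 and FLT1 depend on the background floor, as does that of NDRG1.

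Of the 39 lists tested, 17 passed with the preset correlation, 6 higher and 11 lower. With a correlation estimated per list from 4 residual degrees of freedom, camera called 0 lists (7 at an unadjusted p under 0.05, lowest adjusted p = 0.128), while fry, which asks only whether a list's own genes moved one way on balance, called 28. Over the 17 lists, the estimated correlation ran from -0.0196 for interferon response genes to 0.588 for histone genes, compared with the preset 0.01. It was 0.196 for the integrated stress response list, which had the smallest camera adjusted p. With 3 arrays per group, which correlation is right cannot be told.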

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

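The comparison within bins of intensity was chosen after the result was seen; the other tests of this part were set before. With 3 arrays per group no formal test for an outlying array was run, and the series has 1 contrast, so differences between contrasts do not arise.

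A signal stood out in data that no comparison above used, the 98455 rows without a gene name here. In the fit over all rows, 5565 of them were higher and 1331 lower with CX-4945, so 80.7% of the called unnamed rows were higher, compared with 43.9% of the called named rows. Scaling between arrays as the whole cause is argued against by quantile normalization, after which 66.6% of the called unnamed rows were still higher, although that step took away part of the excess. Dimness of these rows is argued against as well, since over 10 equal bins of intensity, in each of the 6 bins with at least 100 calls of both kinds, the share of rises was at least 25.7 points greater in unnamed than in named rows. A single aberrant array is argued against because the lowest share, without CX-4945 replicate 3, was 77.1%. What the rows are was not tested: unspliced or noncoding RNA that accumulates with CX-4945 may account for the excess, and so may probe properties of unnamed rows or the authors' summarization.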

How the results depend on the processing

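The filter at the olfactory receptor level was chosen after the data were seen. Without moderation 4259 genes were called changed (7665 with it), 1692 higher (3469) and 2567 lower (4196), and the log2 difference of NR5A1, -1.768 in both, no longer passed (adjusted p 0.0628; 4.31e-06 to 0.0628 over its alternatives). This fit has fewer degrees of freedom and takes each gene's own variance, and the share of each in the lost calls was not tested. Over all rows, which adds the unnamed ones, 13399 were changed, 8421 higher and 8552 at least 2-fold (3816 for genes). The 17 gene lists became 0 with an estimated correlation, which asks the same question as the main list test with another correlation. They became 28 with fry, which asks a different question. Testing against a fold of 1.2 with treat left 5005 changed genes, since it asks for more than a difference from 0. In the other alternatives run for them, these counts stayed within 1.5 times and NR5A1 kept its direction and call. Leaving out each array gave 5865 to 8921 changed genes, 2542 to 4226 higher, 3318 to 4695 lower, 3759 to 4111 at least 2-fold, 14 to 17 lists and -2.087 to -1.585 for NR5A1. Of the left-out arrays, CX-4945 replicate 2 gave the highest count of changed genes, and array weights gave 9362; the cause was not tested here. Shared calls in the same direction were 89% of the 7665 after quantile normalization, 74.8% without DMSO replicate 2 and 52.6% without moderation. Among single named genes, 2387 values under an alternative kept direction and side of the threshold, 43 lost the call, 5 gained it and 21 uncalled values changed sign; among lists the numbers were 601, 41, 14 and 7. No called value reversed.

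Whether the replicate numbers pair the arrays cannot be told from 3 arrays per group. Deviations from the group means of same-numbered arrays correlated at 0.09, 0.09 and -0.04. Between arrays of different number they correlated at -0.14 to 0.05, and not every array correlated best with its own number. With the replicate number as a block, 8058 genes were changed, 3705 higher, 4353 lower and 3824 at least 2-fold, and 17 lists passed. NR5A1 was at -1.768, which a balanced block cannot change. Its limma adjusted p was 2.85e-05 with the block and 3.87e-04 without it.

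The 6 arrays can be split in 10 ways, too few for a share under 0.05. For each count, 1 of the 10 splits, the real one, gave a count as large. The real split gave 7665 changed, 3469 higher, 4196 lower and 3816 at least 2-fold, with a highest of 0 in the other splits. It gave 17 lists, with a highest of 14 in the others. Each other split, however, sets 2 arrays of a group and 1 of the other against the rest. The treatment difference then widens the spread within its groups, which by itself holds down the calls of genes. Part of that difference also remains between its groups. Neither the counts of 0 nor these lists therefore say anything of the test's errors. Signal over background limits what can be read: 17337 of 33616 genes lay above the olfactory receptor level in a group.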

Other observations

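The gene families, the genes on 1 side of the background level and the genes named from them were chosen after their values were seen, as were the tests of dimness by separate bins of intensity, of mixed RNA on the deepest falls and of calls among hosted small RNA genes. Families were formed from symbol roots among genes in no list fixed beforehand, and camera with the preset correlation called 33 of 323 families with at least 8 members. None passed with an estimated correlation (adjusted p 0.695 or higher). Correlation between genes bears on the counts of members too, so these only describe families chosen by their values. Among all 17579 protein-coding genes, 2094 were higher and 3575 lower. Genes of intraflagellar transport, which build cilia, were lower in 13 of 18 and higher in none, before and after quantile normalization. The log2 differences of IFT122, IFT81 and IFT88 were -2.81, -2.37 and -2.10. Of 8 Bardet-Biedl genes, which also serve cilia, 4 were lower, with BBS2 at -1.90. APOBEC cytidine deaminase genes, which resemble one another in sequence, were lower in 6 of 9, with APOBEC3F at -2.65 and APOBEC3B at -2.26. Genes with COQ symbols, named after coenzyme Q (ubiquinone), were lower in 8 of 11, with COQ10A at -1.92, while COQ10B rose by 1.39. Of the beta subunits of the proteasome 6 of 11 were lower, among them the immune subunits PSMB8 at -2.44 and PSMB9, which fell to below background. The median of each of these families kept its direction under both other scalings.

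Zinc finger genes named ZNF went the other way, with 182 of 485 higher and 34 lower (154 and 50 after quantile normalization). ZNF597 rose by 2.61 and ZNF773 by 2.50. Taste receptor genes were higher in 9 of 25 and lower in none (6 and none after quantile normalization), with TAS2R3, from below background, at 3.03, TAS2R4 at 2.89 and TAS2R5 at 2.12. Of 8 genes of the NPIPB family, whose copies are nearly identical, 6 were higher, with NPIPB6 at 0.99. Among the genes called changed, 227 lay above the olfactory receptor level on all 3 treated arrays and on no DMSO array, 116 of them protein-coding, and 278 the reverse, 224 protein-coding. Among the former were the matrix proteases MMP10 (log2 difference 4.23) and MMP1 (3.74) and cyclin CCND1 (3.18). Among the latter were the calcitonin receptor CALCR (-4.64) and FHL2 (-3.61), and all of these differences depend on the background floor.

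Of 220 snoRNA genes, 39 were higher and 7 lower, and of 1470 microRNA genes 86 were higher and 25 lower. After quantile normalization the H/ACA class (SNORA) had 11 higher and 1 lower of 69 and the C/D class (SNORD) 12 and 9 of 149. The microRNA genes then had 53 and 39, and their median log2 difference went from 0.08 to -0.03, so most of their lean depended on the scaling. RNA of host introns read by these rows may contribute, and the tests of it differed, so it stays open. The median log2 difference of the 748 genes inside a protein-coding or lncRNA gene above background lay 0.0452 above that of the other 942 (95% bootstrap interval 0.00952 to 0.0737; hosts on either strand), below the bound of 0.1 set beforehand, and 0.02 above it among genes over background. Higher calls made up 9.63% of the hosted genes and 5.63% of the others (two-sided Fisher's exact test over genes, which are not independent, p = 0.00198), and 15.5% and 9.25% among those above background (p = 0.0157). With 72 of the 748 hosted genes called higher, a median can miss a shift of that minority, which is why the bound on it does not settle the matter.

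Protein-coding genes with the longest span in the genome leaned lower than the others. Of 11143 above background, the longest eighth (from 141.4 kb) had a median log2 difference of -0.35, with 197 higher and 573 lower, and lay 0.24 below the other genes (gap -0.24, 95% bootstrap interval -0.31 to -0.18, over genes, which are not independent). The shorter eighths had medians of -0.14 to -0.07, with no steady trend by span among them. Dimness of the long genes is argued against in the 3 brighter of 4 equal bins of intensity, where the weakest gap was -0.24 (-0.39 to -0.11); in the dimmest bin, -0.16 (-0.33 to -0.04), it cannot be told apart from a real gap, which left the test as first set, over every bin, undecided. A single aberrant array is argued against by the weakest gap without any 1 array, -0.17 (-0.23 to -0.11), found without CX-4945 replicate 2. Slower transcription, which would show first in long genes, may account for the gap and was not tested, nor was the class of proteins that long genes encode.

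CX-4945 replicate 2 lay apart from the other treated arrays, with an array weight of 0.397 compared with 0.89 and 1.67. A weaker response stays open. Among genes that differed at least 2-fold on the other treated arrays, the slope of its response on theirs was 0.87. It ranged from 0.84 to 0.90 over the choices of a held-out DMSO array, and 1 of these 3 slopes lay above the bound of 0.9 set beforehand. Replicates 1 and 3 had mean slopes of 0.96 and 0.98. Within rises alone the slopes of replicate 2 were 1.008 to 1.063, compared with 0.966 to 1.015 on replicates 1 and 3. Within falls alone they were 0.955 to 0.976, compared with 0.992 to 1.023. The pooled slope therefore does not show a response weaker in proportion among the rises. Genes that rose 2-fold to 4-fold on the other arrays did fall short on replicate 2, by a median of 0.33 to 0.36. On replicates 1 and 3 that shortfall was 0.0054 to 0.19. Untreated RNA was first tested by the shortfall of genes that rose at least 16-fold, which averaged 0.16 and by the bound set beforehand went with mixing, although it was 0.17 on replicate 1. The test that replaced it, after that result, argues against mixing as the whole cause: the shortfall of genes that fell 2-fold to 4-fold would need 8.15% to 10.8% of untreated RNA, which would hold the deepest falls at -3.62 or above, whereas genes that fell at least 16-fold on the other arrays had a median of -4.48 on this one. Smaller shares of untreated RNA are not excluded, and the same deep genes fell short on this array by 0.30 to 0.53, compared with -0.27 to 0.0011 on replicates 1 and 3, which goes the way of mixing or of a weaker response.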
